A study of Mus musculus with 9 samples.

How the data were processed

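Gene expression was measured in germinal center (GC) B cells of mice on 9 Affymetrix Mouse 430.2 arrays. GC B cells are the antigen-activated B cells that divide and mutate their antibody genes in the follicles of lymphoid organs. Per the labels' protocols, 10-week-old mice received repeated injections of sheep red blood cells, and spleens were taken on day 12. GC B cells were sorted from B cell-enriched spleen cells by surface staining (B220 high, PNA high, CD95 high). Every animal carried Cg1-Cre, a recombinase switched on in GC B cells. The labels gave 3 genotypes: FOXO1+/+ (WT), FOXO1f/+ (HET, 1 floxed allele) and FOXO1f/f (KO, 2 floxed alleles), with 3 arrays each. Per the labels, each array held RNA of 1 single animal, while the series' design text speaks of pools of spleen cells. The sample titles carry a number each, and no 2 genotypes share one, so arrays were numbered within a genotype in the order of deposition and were not paired. Sex, litter and array batch were not given in the sources used here. RNA was amplified with a NuGEN kit before biotin labelling, per the labels' protocols.

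The deposited table held 1 intensity (signal) per probe set and array on a linear scale. The authors processed the arrays with MAS5, per the submitters' processing notes, and the version was not given in the sources used here. MAS5 summarises the probes of a probe set and scales each array to a fixed trimmed mean: the mean signal after trimming 2% at each end was 500 on every array. The median signal per array lay between 42.9 and 48.0: from 47.4 to 48.0 on the KO arrays and from 42.9 to 45.0 on the WT and HET arrays. For arrays, the precision is limited by their number.

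The table held 45101 probe sets, of which 64 were control probe sets. The platform annotation gave exactly 1 gene symbol to 34945 probe sets, several symbols to 932 and none to 9160. Of the probe sets with 1 symbol, 34741 were matched by Entrez identifier to the RefSeq genes of GRCm38.p6, and 0 symbols changed. Since no genome build is named for the table, no coordinates are printed, and the RefSeq table served for names and for the order of genes along a chromosome. The place of each Foxo1 probe set relative to the floxed segment was not analysed here. Some listed genes, among them genes without a probe set of a single symbol, were not analysed here.

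Signals were analysed as log2(signal + 2.09), where 2.09 was the 10th percentile of all signals, so that changes of dim genes are understated. No further normalization between arrays was applied. A probe set was kept when it reached its array's median in at least 3 of the 9 arrays, which left 19479 probe sets. Each gene was represented by its kept probe set with the highest mean, giving 10331 genes. Linear models were fitted over all 9 arrays with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and every adjusted p in the text comes from limma. The contrasts were KO vs WT, HET vs WT, KO vs HET, the slope per floxed allele (coded 0, 1 and 2) and the departure of HET from the midpoint of WT and KO. Where a gene lay below the array median on all arrays of a group, it was called dim there, and a fold is given as "at least", against the higher of its own signal and the array median. Where only some arrays of a group lay below it, their number is given.

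A total of 36 gene lists holding 626 genes were written from general knowledge of GC B cells before the data were examined, as were the main model, the alternatives and the rule for naming genes. Of these genes, 562 had a probe set with 1 symbol. The 30 lists with at least 5 tested members (Foxo1 left out) were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, stand beside it. The other lists had fewer tested members and were not tested: immunoglobulin constant regions (3), T cell (4), NK cell (2), erythroid and platelet (1) and stromal markers (2), and a list of sex chromosome genes, left out as it follows the sex of the animals.

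Genes are named by this rule: a fixed list of GC and FOXO1 genes; for KO vs WT the 8 largest rises and 8 largest falls among called genes whose KO and WT arrays do not overlap (4 each way for the other pairs), leaving out sex chromosome genes, unnamed gene models and antibody variable segments; up to 4 members of each list with the smallest adjusted p; and the 4 genes with the largest moderated t for the HET departure. Where too few genes passed, the largest t filled the places. Other genes are said to be chosen after their values were seen.

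The model was tested on simulated data drawn from the real means and residual spreads, with known changes added. Of 50 genes simulated with a KO vs WT log2 change of 0.60, 58.0% were recovered, and of 50 with 1.00, 90.0%, with 11 false calls over 10279 genes tested. In the same data, 22.0% of 50 genes with a HET vs WT log2 change of 0.30 and 52.0% of 50 with 0.50 were recovered, with 5 false calls. The number of changed genes sets how strict the adjusted cutoff is. The real HET vs WT contrast had 1 call and thus a stricter cutoff, so these shares are too high for it. For KO vs HET, 18.0% of 50 genes at 0.30 were recovered. The real KO vs WT and KO vs HET contrasts had 1232 and 929 calls, more than the genes changed in the simulation. Their cutoffs were thus easier, and the simulated shares may be too low for them. Alternatives covered the offset, a floor, quantile normalization, median centring, the filter, the choice of probe sets, the variance model, array weights, fits of 6 arrays and leaving out each array. Chosen after seeing the data were a block for the Xist signal and leaving out the genes on the chromosome of Foxo1. Intervals of list medians and of the differences between KO and a HET array left out of the choice of genes came from a bootstrap over genes, which are not independent. Further lists of myeloid genes and of genes of B cells outside the GC were written after the first results and before their own values were looked at. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.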

Results

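Transcript levels were measured in GC B cells sorted from mice with 2 intact Foxo1 alleles (WT), 1 floxed allele (HET) or 2 floxed alleles (KO), with 3 arrays in each group and, per the sample labels, 1 animal per array. Foxo1 encodes a forkhead transcription factor that PI3K and AKT signaling keeps out of the nucleus. The 9 arrays gave 10331 genes for testing. Correlations between arrays of the same group lay between 0.984 and 0.990 over log2 signals, and those between arrays of different groups between 0.974 and 0.990. The first principal component held 36.9% of the variance and parted the KO arrays from the others. The log2 ratio of the 3' to the 5' Actb control probe sets was 1.16 ± 0.08 in WT, 1.17 ± 0.07 in HET and 1.19 ± 0.07 in KO (SD, n = 3; exact permutation p = 0.70 for KO vs WT, 0.80 for HET vs WT and 0.80 for KO vs HET; the smallest possible is 0.10). For Gapdh it was 0.707 ± 0.019 in WT, 0.691 ± 0.026 in HET and 0.727 ± 0.020 in KO (SD, n = 3). The exact permutation p for Gapdh was 0.30 for KO vs WT, 0.40 for HET vs WT and 0.20 for KO vs HET.

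The targeted gene came first. The brightest of 4 Foxo1 probe sets gave a signal of 5449 ± 159 in WT, 3564 ± 77.9 in HET and 1034 ± 335 in KO (SD, n = 3). The KO mean was 19.0% of WT and the HET mean 65.4% of WT. Foxo1 fell by 2.45 on the log2 scale in KO vs WT (SE 0.16, adjusted p = 2.31e-06). The HET vs WT change of -0.61 (SE 0.16) did not pass (adjusted p = 0.919), although all 3 HET arrays lay below all 3 WT arrays. The next 2 probe sets by brightness gave KO means of 17.6% and 15.9% of WT and HET means of 59.9% and 55.5% of WT. The dimmest probe set gave 50.9 ± 6.13 in WT, 78.5 ± 12.8 in HET and 69.2 ± 13.6 in KO (SD, n = 3) and was not lower in KO. Whether a probe set lies inside the deleted segment was not analysed here, and one outside it would not check the genotype. The related Foxo3 (0.14, adjusted p = 0.257) and Foxo4 (0.19, adjusted p = 0.264) did not pass in KO vs WT.

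**Figure D1:**
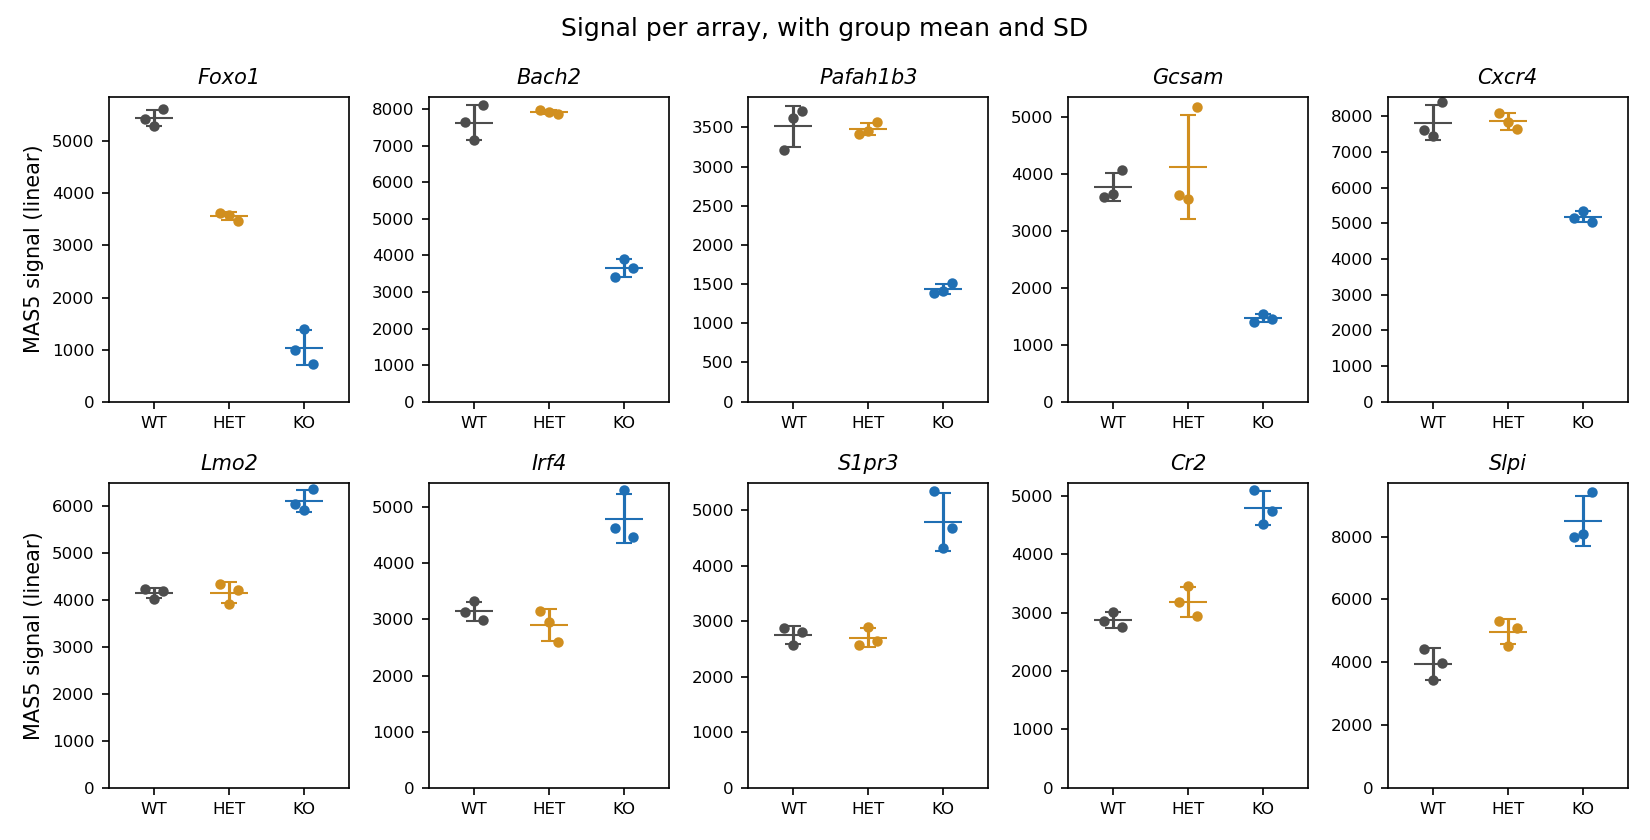
MAS5 signal on a linear axis for Foxo1 and 9 other named genes in WT, HET and KO arrays; points are single arrays, and the horizontal line and bar are the mean and SD (n = 3). Foxo1 steps down from 5449 in WT to 3564 in HET and 1034 in KO, while Bach2, Pafah1b3, Gcsam and Cxcr4 are lower, and Lmo2, Irf4, S1pr3, Cr2 and Slpi higher, in the 3 KO arrays than in the other 6.

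KO vs WT is the comparison named by the series title: GC B cells of mice with 2 floxed Foxo1 alleles against cells with both alleles intact. In KO cells, 7 of 14 genes linked to the dark zone, the GC area where B cells divide and mutate, were lower. Of the marginal zone B cell markers 9 of 10 were higher, as were 7 of 18 plasma cell genes (for that list, adjusted p = 0.474 with an estimated correlation). The light zone genes, linked to the area where B cells are selected by T cells, moved both ways. In all, 1232 of 10331 genes changed, 630 up and 602 down. Of these, 227 changed over 2-fold, 124 up and 103 down.

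Of the 8 largest rises in KO by the naming rule, which leaves out unnamed gene models, 6 were of genes dim in WT. Nhsl1 went from 10.8 ± 0.784 to 352 ± 105 (SD, n = 3), at least 7.53-fold higher (adjusted p = 5.60e-05). Stum rose at least 6.72-fold (adjusted p = 2.07e-05), Srgap3 at least 3.08-fold (adjusted p = 2.85e-04) and Dse at least 2.30-fold (adjusted p = 2.56e-04). Nhsl1, Stum, Srgap3 and Dse passed the filter only through the 3 KO arrays. The fits that left out a KO array therefore did not test them, and the other 6 fits that left out 1 array called each. Rai2 rose by 2.85 on the log2 scale (SE 0.50, adjusted p = 0.00272), with 1 of 3 WT arrays below the array median. Slco3a1 (39.1 ± 65.0 in WT, with 2 of 3 arrays below the array median, and 284.7 ± 47.6 in KO; SD, n = 3; limma adjusted p = 0.0248), Gprc5b (at least 3.07-fold, adjusted p = 0.0488) and Col6a3 (at least 2.78-fold, adjusted p = 0.0348) also rose. These 3 calls were lost in 5, 6 and 5 of the 9 fits that left out 1 array, with adjusted p up to 0.108, 0.141 and 0.122, and in eBayes without trend (adjusted p = 0.0909, 0.131 and 0.103) and robust eBayes (adjusted p = 0.142, 0.174 and 0.138). That of Gprc5b was also lost with no offset, quantile normalization, no filter, array weights and the Xist block (adjusted p = 0.0517, 0.0578, 0.0749, 0.0601 and 0.0507), and that of Col6a3 without the filter (adjusted p = 0.0543). Single HET arrays exceeded every KO array: Gprc5b was 313.4, 6.74 and 3.92 on HET replicates 1, 2 and 3, and Col6a3 was 16.1, 67.6 and 419.3. Among the largest falls beside Foxo1, the stem cell receptor gene Lgr5 went from 92.7 ± 11.6 to 15.4 ± 12.0 (SD, n = 3; at least 1.90-fold lower, adjusted p = 0.00686). The zinc finger gene Zkscan16 fell by 2.61 (SE 0.20, adjusted p = 6.63e-06). The receptor tyrosine kinase gene Ret fell from 239 ± 41.6 to 36.1 ± 20.5 (limma adjusted p = 0.00278) and Dlg5 from 307 ± 94.8 to 59.6 ± 28.4 (SD, n = 3; limma adjusted p = 2.62e-04), each with 2 of 3 KO arrays below the array median. Fbxw13, Art4 and Adgb were dim in KO and at least 1.16-fold, 1.12-fold and 2.40-fold lower (adjusted p = 0.00473, 0.00397 and 1.09e-04), and 1 of 3 WT arrays of Fbxw13 and of Art4, like 1 of 3 KO arrays of Col6a3, lay below the array median.

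Of 14 tested dark zone genes outside the cell cycle, 7 fell and 7 did not pass (8 fell and 1 rose adjusted over the list alone). As a list they were lower in KO than other genes (camera adjusted p = 5.87e-08), with adjusted p = 0.0218 with an estimated correlation. Gcsam, a GC-restricted regulator of B cell motility, fell by 1.36 (SE 0.12). Pafah1b3, a lipid enzyme gene, fell by 1.29 (SE 0.067) and Bach2, a repressor of plasma cell fate, by 1.06 (SE 0.061). Cxcr4, the chemokine receptor that holds B cells in the dark zone, fell by 0.59 (SE 0.05), from 7818 ± 498 to 5182 ± 158 (SD, n = 3). Of 26 light zone genes, 7 rose, 3 fell and 16 did not pass (7 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.255). Lmo2 rose by 0.56 (SE 0.06), Irf4 by 0.61 (SE 0.08) and Cd86, a ligand for T cell costimulation, by 0.41 (SE 0.07). Fcer2a, which encodes CD23, fell by 0.76 (SE 0.07), and Batf, a factor needed for antibody class switching, by 1.32 (SE 0.20). Cd83 (-0.14, adjusted p = 0.334) and Myc (0.17, adjusted p = 0.305) did not pass.

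**Figure D2:**
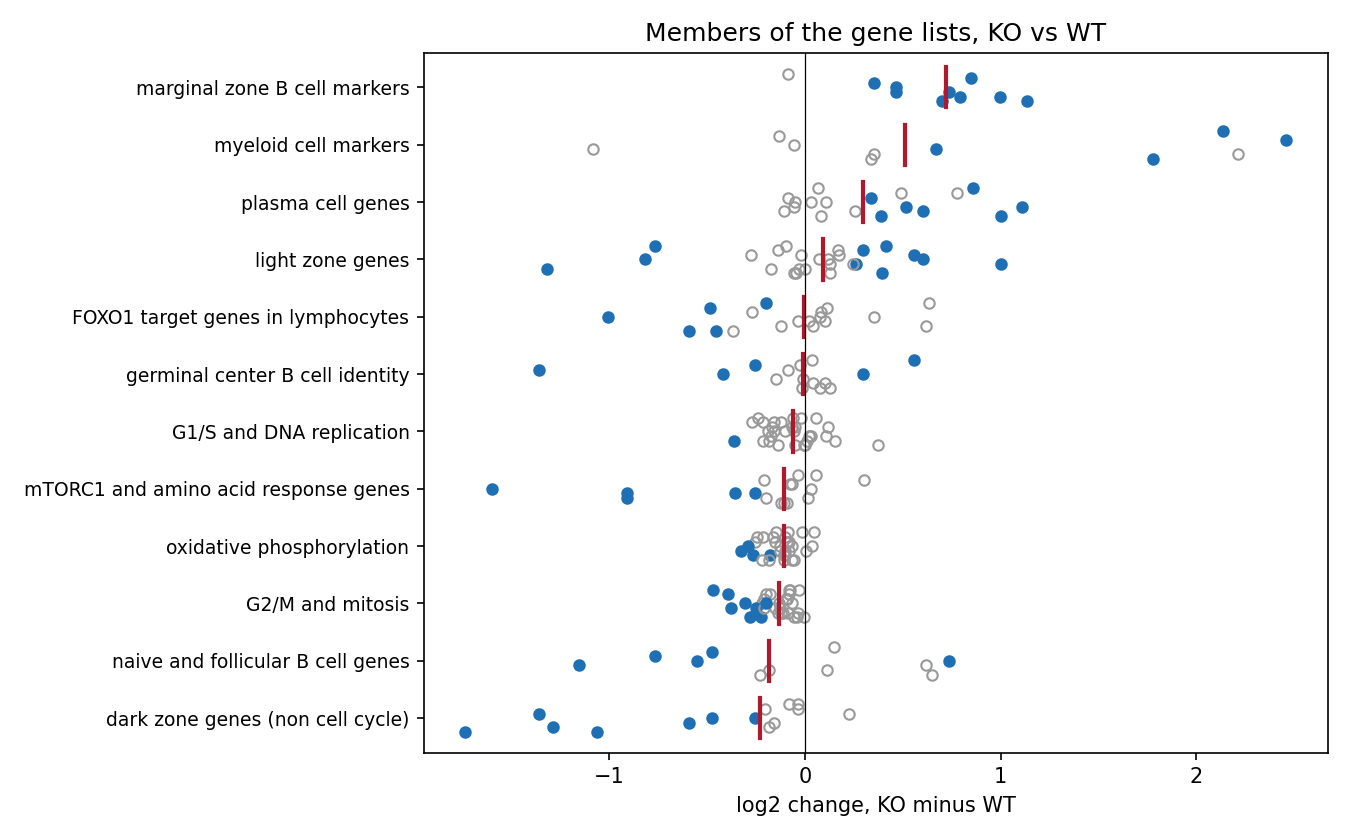
Log2 change in KO minus WT for each tested member of 12 gene lists; each point is a gene, filled where its adjusted p is under 0.05, and the red bar is the median of the list. The dark zone list has its median at -0.23 and the marginal zone list at 0.72, while light zone genes lie on both sides of 0.

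Of 10 marginal zone B cell markers, 9 rose and 1 did not pass (9 rose adjusted over the list alone), with a median log2 change of 0.72 (camera adjusted p = 1.36e-07; adjusted p = 0.0218 with an estimated correlation). Marginal zone B cells are a splenic population outside the follicle. S1pr3, a sphingosine phosphate receptor gene, rose by 0.79 (SE 0.08) and Cr2, which encodes the complement receptor CD21, by 0.74 (SE 0.07). Plac8 rose by 1.14 (SE 0.17) and Dtx1, a target of NOTCH2, by 0.47 (SE 0.07). Of 18 plasma cell genes, 7 rose and 11 did not pass (7 rose adjusted over the list alone; camera adjusted p = 7.66e-04; adjusted p = 0.474 with an estimated correlation). Slpi rose by 1.11 (SE 0.09), Edem1 by 0.52 (SE 0.07), Irf4 by 0.61 and the elongation factor gene Ell2 by 0.34 (SE 0.06). Prdm1, which encodes the plasma cell factor BLIMP1, rose by 0.86 (SE 0.17, adjusted p = 0.00686). Markers of other cells rose, fell or did not pass, depending on the list. The filter kept 10 of 23 myeloid, 5 of 12 dendritic and 4 of 17 T cell markers on the array, so most of them were too dim to be tested. Of 10 myeloid cell markers, 4 rose and 6 did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.0486; adjusted p = 0.533 with an estimated correlation). Cd68 rose by 0.67 (SE 0.13), Lyz2 by 1.78 (SE 0.40) and Lyz1 by 2.13 (SE 0.61), and Csf1r went from 53.6 ± 53.8, with 2 of 3 WT arrays below the array median, to 232.6 ± 86.2 (SD, n = 3). With the mean of its 3 probe sets, which ranged from 0.25 to 2.46, the change of Csf1r was 1.26 and not called (adjusted p = 0.0936). On HET replicate 3 Csf1r stood at 488.8, above every KO array. The calls of Lyz2, Lyz1 and Csf1r were lost in 3, 5 and 5 of the 9 fits that left out 1 array (adjusted p up to 0.0606, 0.146 and 0.153) and in eBayes without trend (adjusted p = 0.0522, 0.120 and 0.115), and those of Lyz1 and Csf1r in robust eBayes (adjusted p = 0.181 and 0.164), without the filter (adjusted p = 0.0602 and 0.0609) and with array weights (adjusted p = 0.0671 and 0.0615). Lyz2 stood at 102 ± 59.8 in WT and 334 ± 113 in KO (SD, n = 3). The myeloid call was lost without WT replicate 2 or 3, KO replicate 1 or 2, or HET replicate 1 (adjusted p = 0.0826, 0.141, 0.0794, 0.0674 and 0.0580). It was also lost under quantile normalization, without the filter, with the mean of a gene's probe sets, with the Xist block and with fry (adjusted p = 0.0516, 0.161, 0.0647, 0.0589 and 0.110; range over all settings 0.00661 to 0.533). Of 5 dendritic cell markers, Sirpa rose by 0.65 (SE 0.10) and 4 did not pass (2 rose adjusted over the list alone; adjusted p = 0.496); their median was -0.041, while their mean was 0.20 and the test pointed up. Of 4 T cell markers, Cd2, which B cells also express, fell by 1.16 (adjusted p = 5.70e-07), and Lat, Cd8a and Thy1 did not pass (2 fell adjusted over the list alone). Of 2 NK cell markers, limma called 0 (0 at an unadjusted p under 0.05 and 0 adjusted over the list alone). Of 2 stromal markers it called 0 as well, with 1, Pecam1 (0.44, adjusted p = 0.0781), at an unadjusted p under 0.05 and higher adjusted over the list alone. Car2, the 1 erythroid marker tested, fell by 0.77 (adjusted p = 0.0316; 1 adjusted over the list alone). Of 3 antibody constant region genes, Ighm rose by 0.39 (adjusted p = 0.00297) and 2 did not pass (1 rose and 1 fell adjusted over the list alone). Of 5 B-1 B cell markers, 3 fell and 2 did not pass (3 fell and 1 rose adjusted over the list alone; adjusted p = 0.194); Spn fell by 1.28 (SE 0.18) and Plscr1 by 1.01 (SE 0.19).

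Of 6 cell cycle and metabolic lists, 4 were called lower in KO, each call lost with an estimated correlation, and the lists of glycolysis and of quiescence and cell cycle inhibitors were not called (adjusted p = 0.519 and 0.639). Of 32 G2/M and mitosis genes, 8 fell and 24 did not pass (9 fell adjusted over the list alone), with a median of -0.13 (camera adjusted p = 1.15e-07; adjusted p = 0.22 with an estimated correlation). Ccna2, which encodes cyclin A2, fell by 0.47 (SE 0.055) and the phosphatase gene Cdc25b by 0.38 (SE 0.054). Cenpa, a centromere histone gene, fell by 0.39 (SE 0.07), and its call was lost without the probe sets of shared suffix (adjusted p = 0.789) and with the mean of its probe sets (adjusted p = 0.217; range over all settings 0.00186 to 0.789). Of 31 G1/S and replication genes, Pola1 fell by 0.36 (SE 0.06) and 30 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.533 with an estimated correlation). That list's call was lost without WT replicate 3 (adjusted p = 0.0756), without KO replicate 3 (adjusted p = 0.323) under quantile normalization (adjusted p = 0.25), with a stricter filter (adjusted p = 0.0746) and with fry (adjusted p = 0.105). Of 31 oxidative phosphorylation genes, 4 fell and 27 did not pass (9 fell adjusted over the list alone; camera adjusted p = 6.99e-06; adjusted p = 0.385 with an estimated correlation). Sdhb fell by 0.29 (SE 0.061), Ndufa4 by 0.27 (SE 0.065), Uqcrq by 0.33 (SE 0.082) and Atp5b by 0.18 (SE 0.051). The last 3 calls were lost in 4, 4 and 8 of the 9 fits that left out 1 array (adjusted p up to 0.0756, 0.0904 and 0.141) and in eBayes without trend (adjusted p = 0.0647, 0.0564 and 0.124), that of Atp5b also under quantile normalization, without the filter and with the Xist block (adjusted p = 0.0536, 0.0840 and 0.0553). The change of Uqcrq was 0.16 with the mean of its probe sets (adjusted p = 0.36; range over all settings 0.0080 to 0.36). Of 17 mTORC1 and amino acid response genes, 5 fell and 12 did not pass (5 fell adjusted over the list alone; camera adjusted p = 0.00243; adjusted p = 0.119 with an estimated correlation). The named members that fell, picked for the smallest adjusted p, are known targets or parts of the ATF4 amino acid response: Asns by 0.91 (SE 0.09), Psat1 by 0.36 (SE 0.07) and Atf4 by 0.25 (SE 0.05), with Chac1 at least 2.22-fold lower. ATF4 targets were not tested as a list. The cyclin genes Ccnd3 (-0.18, adjusted p = 0.161) and Ccnd2 (0.37, adjusted p = 0.248) did not pass.

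Most genes that define GC B cells did not pass the test, although the share called was above that over all genes (1232 of 10331). A gene that did not pass may still have changed: of simulated genes with a KO vs WT log2 change of 0.30, 30.0% were recovered. That share may be too low for the real data, where more genes changed. Of 15 GC identity genes, 2 rose, 3 fell and 10 did not pass (2 and 3 adjusted over the list alone; adjusted p = 0.623). Bcl6, the master factor of GC B cells, stood at 9163 ± 1358 in WT and 9376 ± 268 in KO (SD, n = 3; log2 change 0.043, SE 0.079, adjusted p = 0.793). Neil1 fell by 0.42 (SE 0.06). Fas, whose protein CD95 was a sorting marker, rose by 0.30 (SE 0.07), and its call was lost without WT replicate 2 (adjusted p = 0.0509). Of 18 reported FOXO1 targets in lymphocytes, 5 fell and 13 did not pass (5 fell adjusted over the list alone). As a list they were not called by camera (adjusted p = 0.197), while fry, which does not compare a list with other genes, called them lower (adjusted p = 0.0115). Insr, the insulin receptor gene, fell by 1.01 (SE 0.22), the cell cycle inhibitor gene Cdkn1b by 0.49 (SE 0.10) and Bcl2l11, which encodes the death inducer BIM, by 0.45 (SE 0.07). The migration regulators Klf2 (0.11, adjusted p = 0.764) and S1pr1 (0.62, adjusted p = 0.294; 2 WT arrays and 1 KO array below the array median) did not pass. Gpr183, a receptor that guides B cells within follicles, had a change of 0.15 (adjusted p = 0.738). Of 11 naive and follicular B cell genes, 4 fell, 1 rose and 6 did not pass (4 fell and 2 rose adjusted over the list alone; adjusted p = 0.173). Satb1 fell by 0.55 (SE 0.09) and Foxp1 by 0.48 (SE 0.08), or by 0.95 with the mean of its probe sets.

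Across these lists, 8 of 30 were called in KO vs WT, and 2 of the 8 (dark zone, marginal zone) were called with an estimated correlation. Fry called 8 as well, without the G1/S and myeloid lists and with the FOXO1 targets and the B cell receptor signaling genes (adjusted p = 0.0150). Other splits of the KO and WT arrays into 3 and 3 gave 0 to 10 lists called by camera and at most 1 called gene. At the preset correlation, camera thus also called lists with the genotypes mixed, and the number of called lists alone does not show a difference. The count of 1232 genes came to 770 without WT replicate 2 and 768 without WT replicate 3. With each array centred on its median, 495 genes were higher and 716 lower. The KO arrays had higher median signals (47.4 to 48.0) than the WT and HET arrays (42.9 to 45.0), so the balance of rises and falls depends on the scaling.

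HET vs WT asks how cells with 1 floxed allele differ from cells with none. A single gene changed, Gm34303, a gene model next to Foxo1 in the order of tested genes. Its signal was 68.2 ± 8.49 in WT, 1956 ± 222 in HET and 2985 ± 518 in KO (SD, n = 3), a log2 rise of 4.80 in HET vs WT (SE 0.14, adjusted p = 9.44e-10). Genes of the GC, dark zone and marginal zone lists that changed in KO did not pass in HET: the log2 difference of HET from WT was 0.056 for Bach2, 0.0077 for Cxcr4, 0.11 for Gcsam, -0.12 for Irf4 and -0.024 for S1pr3 (adjusted p = 0.998 for each). With limma, 432 of 10331 genes had an unadjusted p under 0.05, a share below the 0.05 that no difference at all would give. The count of 1 came to 2 without WT replicate 3, 2 without KO replicate 3 and 3 without HET replicate 2. The genes of largest t that did not pass were, upward, Slc30a4 (0.65, adjusted p = 0.0759), Polr3gl (1.64, adjusted p = 0.242), Cdk13 (0.42, adjusted p = 0.318) and Bcl9 (0.62, adjusted p = 0.583). In the other direction they were Anxa9 (dim in HET and at least 1.10-fold lower there, adjusted p = 0.233), Tifa (-1.23, adjusted p = 0.278), Noct (-0.46, adjusted p = 0.501) and Dclre1b (-0.54, adjusted p = 0.680). All of these but Slc30a4 and Cdk13 lie on the chromosome of Foxo1, as does Gm34303. Of the 82 genes with an unadjusted p under 0.01, 20 lay on the chromosome of Foxo1, which is 4.13% of its 484 tested genes against 0.63% of genes elsewhere (odds ratio 6.80, 95% interval 3.86 to 11.5, Fisher's exact p = 7.30e-10 across genes, which are not independent). For KO vs WT another criterion was used, a call at an adjusted p under 0.05, which 1232 genes met. There the odds ratio was 1.13 (95% interval 0.85 to 1.49, Fisher's exact p = 0.351). By the same criterion it was 1.32 in KO vs HET (95% interval 0.97 to 1.76, Fisher's exact p = 0.0727). With so many genes called elsewhere, these values do not show whether a gathering like that in HET vs WT was absent.

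Camera called 4 lists in HET vs WT, in each of which limma called 0 members (0 adjusted over the list alone; 1, 1, 3 and 1 at an unadjusted p under 0.05): naive and follicular genes (median 0.14, adjusted p = 0.0148) and glycolysis (0.061, adjusted p = 0.02) up, and G1/S genes (-0.034, adjusted p = 0.00958) and interferon response genes (-0.21, adjusted p = 0.0432) down. With an estimated correlation 0 were called (adjusted p = 0.348, 0.348, 0.725 and 0.725), and fry called 0. Leaving out HET replicate 1 ended all 4 (adjusted p = 0.0605, 0.183, 0.125 and 0.0605). Without WT replicate 2 the naive, glycolysis and interferon calls were lost (adjusted p = 0.161, 0.112 and 0.822), without WT replicate 3 the G1/S call (0.0714) and without HET replicate 2 the interferon call (0.752). The interferon median was 0.024 without WT replicate 2 and 0.0023 without HET replicate 2, and with the Xist block it was -0.098 and not called (adjusted p = 0.450). Without the filter the naive and interferon calls were lost (adjusted p = 0.0579 and 0.0922), with the mean of a gene's probe sets the naive, glycolysis and interferon calls (adjusted p = 0.102, 0.0725 and 0.0725) and with a stricter filter the interferon call (adjusted p = 0.323), while 9 lists were called without WT replicate 1. Members of these lists with the smallest p included Il4ra (0.22) and Pdk1 (0.28), and Tyms (-0.40) and Usp18 (-0.54), with adjusted p = 0.998.

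The series' 3 genotypes allow an ordering by allele number. The slope per floxed allele was called for 939 genes, 473 up and 466 down; with each array centred on its median, 405 were up and 554 down. Placed on a scale of log2 signals from -1 (WT mean) to 1 (KO mean), the median HET position over the 1232 genes called in KO vs WT was -0.674, and 1145 of them (92.9%) lay nearer to WT. By array, with the KO vs WT genes called without that array where it belonged to WT or KO, the median position was -0.691 ± 0.042 for HET, -0.827 ± 0.094 for WT and 0.722 ± 0.111 for KO (SD, n = 3; exact permutation p = 0.10 for HET against either, the smallest possible). Foxo1 itself lay at -0.50 on this log2 scale. On the linear scale its HET mean was 65.4% and its KO mean 19.0% of WT, which puts HET closer to midway than the log2 position does. HET departed from the midpoint in 103 genes, 66 upward and 37 downward. The 4 of largest t were Gm34303, Bach2, Pafah1b3 and Gcnt3, a mucin-type glycosyltransferase gene with 1192 ± 164 in WT, 1582 ± 154 in HET and 361 ± 33.1 in KO (SD, n = 3). Without WT replicate 2, or HET replicate 1, 2 or 3, the 103 came to 50, 45, 31 and 37. Without KO replicate 1, 2 or 3, the 939 came to 400, 520 and 498.

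KO vs HET compares cells with 2 floxed alleles to cells with 1. In KO, 6 of 14 dark zone genes were lower, and 8 of 10 marginal zone markers and 8 of 18 plasma cell genes were higher. The call of the plasma cell list was lost with an estimated correlation (adjusted p = 0.335 with an estimated correlation). In all, 929 genes changed, 471 up and 458 down. Nhsl1 rose at least 7.41-fold (adjusted p = 2.68e-05), Stum at least 6.62-fold (adjusted p = 3.62e-05) and Srgap3 at least 3.03-fold (adjusted p = 2.97e-04). Il10, which encodes the cytokine interleukin 10, went from 15.6 ± 5.41 in HET to 178 ± 38.7 in KO (SD, n = 3), at least 3.81-fold (adjusted p = 3.38e-05). Like Nhsl1, Stum and Srgap3, Il10 passed the filter only through the KO arrays and was not tested in fits that left out one of them. Parm1 fell by 2.16 on the log2 scale (SE 0.13, adjusted p = 1.20e-06), and Art4 was at least 1.04-fold lower (adjusted p = 0.00574). Rbm44 fell from 179 ± 40.1 in HET to 27.6 ± 45.8 in KO, where 2 of 3 arrays lay below the array median (SD, n = 3; limma adjusted p = 0.0151), and Lgr5 was at least 1.63-fold lower (adjusted p = 0.014). The call of Rbm44 was lost without KO replicate 2 or HET replicate 2 (adjusted p = 0.0604 and 0.0558), in eBayes without trend (adjusted p = 0.0662) and in robust eBayes (adjusted p = 0.101), and that of Lgr5 without HET replicate 1 and in eBayes without trend (adjusted p = 0.0507 and 0.0536).

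In KO vs HET, 6 of 14 dark zone genes fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 6.94e-08; adjusted p = 0.0197 with an estimated correlation). Gcsam fell by 1.47, Pafah1b3 by 1.27, Bach2 by 1.12 and Cxcr4 by 0.60. Of 10 marginal zone markers, 8 rose (9 adjusted over the list alone; camera adjusted p = 6.94e-08; adjusted p = 0.0197 with an estimated correlation), with Plac8 up by 1.23. Of 18 plasma cell genes, 8 rose (8 adjusted over the list alone; camera adjusted p = 4.24e-04; adjusted p = 0.335 with an estimated correlation), among them Prdm1 by 1.19 and Slpi by 0.77. Of 10 myeloid markers, 1 rose (3 adjusted over the list alone; camera adjusted p = 0.247). Of 32 mitosis genes, 7 fell (9 adjusted over the list alone; camera adjusted p = 8.76e-07; adjusted p = 0.194 with an estimated correlation), such as Ccna2 by 0.43. Of 17 mTORC1 and amino acid response genes, 5 fell (5 adjusted over the list alone; camera adjusted p = 0.00127; adjusted p = 0.0965 with an estimated correlation). Of 31 oxidative phosphorylation genes, 1 fell (0 adjusted over the list alone; camera adjusted p = 1.84e-04; adjusted p = 0.334 with an estimated correlation). Of 11 naive and follicular genes, 6 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0154; adjusted p = 0.194 with an estimated correlation), with Fcer2a down by 0.98. Of 18 FOXO1 targets, 3 fell (4 adjusted over the list alone; camera adjusted p = 0.0331; adjusted p = 0.194 with an estimated correlation). Of 20 B cell receptor signaling genes, 4 rose (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.045; adjusted p = 0.334 with an estimated correlation). The FOXO1 target call was lost without KO replicate 1 or HET replicate 2 (adjusted p = 0.0883 and 0.0589) and under quantile normalization and the Xist block (adjusted p = 0.102 and 0.0631), and the receptor signaling call without KO replicate 3, HET replicate 2 or HET replicate 3 (adjusted p = 0.195, 0.0589 and 0.0907) and with median centring and the mean of a gene's probe sets (adjusted p = 0.105 and 0.0600). Fry called 13 lists against 9 by camera, the added ones being memory precursor, glycolysis, apoptosis and BCL6 repressed genes (adjusted p = 0.0171, 0.0129, 0.0268 and 0.0308). The count of 929 came to 543 without HET replicate 2 and 606 without HET replicate 3, and median centring gave 375 higher and 573 lower.

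**Figure D3:**
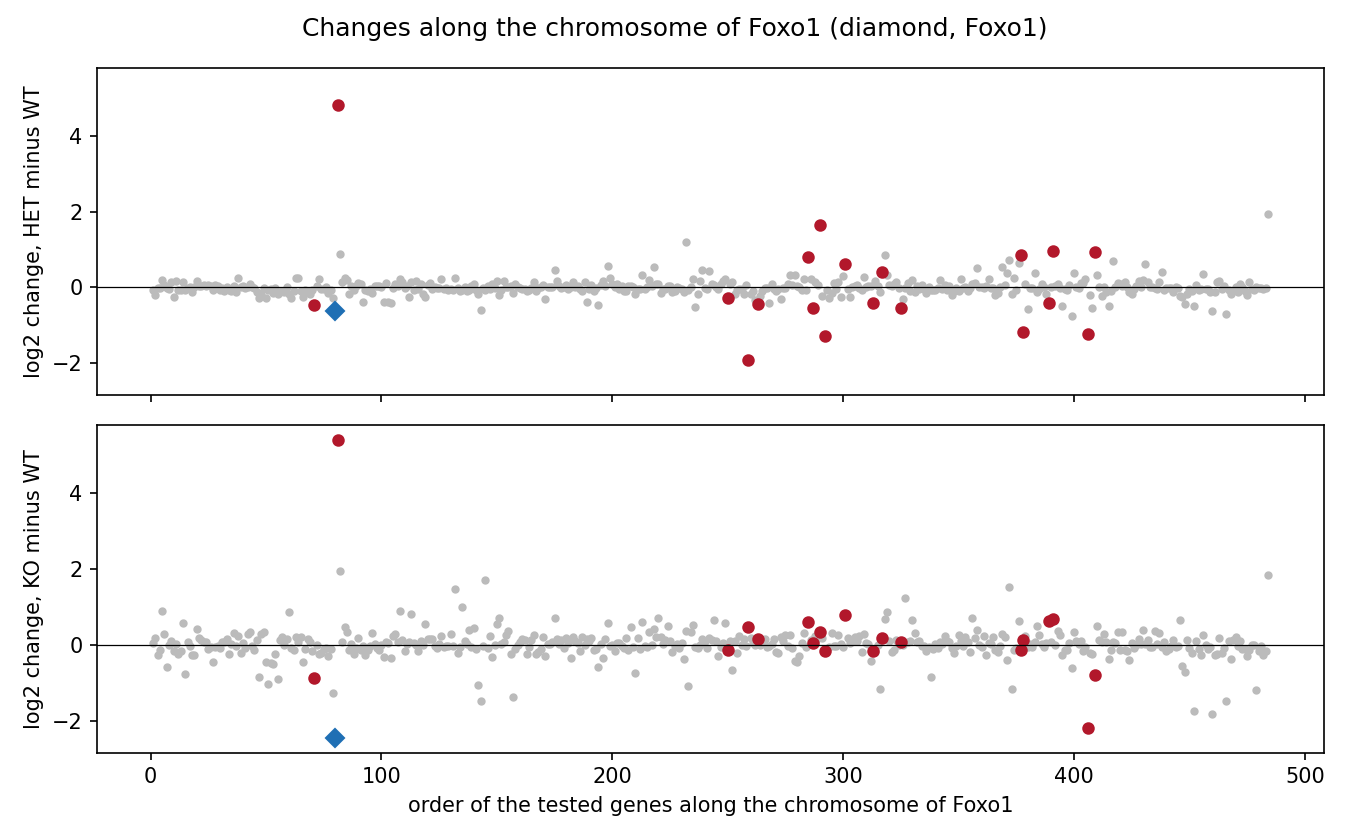
Log2 change in HET minus WT (top) and KO minus WT (bottom) for the 484 tested genes of the chromosome that holds Foxo1, in gene order (x axis, number of tested genes); red points are the 19 genes other than Foxo1 with an unadjusted p under 0.01 in HET vs WT, and the blue diamond is Foxo1. Gm34303 next to Foxo1 is high in both panels.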

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

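The tests of the count of gene lists, of the slope per floxed allele and of the departure of HET from the midpoint, those on the chromosome of Foxo1 and those of array scaling were chosen only after the result was seen.

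Of 3865 tested probe sets that the annotation gives no single gene, 170 changed in KO vs WT, 99 up and 71 down, a signal in data that no gene-level result uses. In 103 genes the change with the first floxed allele differed from that with the second, as tested by the departure of HET from the midpoint of WT and KO, and 13 of them lie on the chromosome of Foxo1.

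Between 3 and 3 arrays, 10 splits are too few for a share under 0.05. For KO vs WT, 1 of 10 splits gave as many genes (real 1232, highest other 1), and 2 gave as many called lists (real 8, highest other 10). For HET vs WT, 2 of 10 splits gave as many genes (real 1, highest other 3) and 5 as many lists (real 4, highest other 11). For KO vs HET, 1 of 10 gave as many genes (real 929, highest other 1) and 1 as many lists (real 9, highest other 6). Over 100 splits of the 9 arrays, 1 gave as many genes for the slope per allele (real 939, highest other 858) and 4 gave as many for the departure from the midpoint (real 103, highest other 1610). In each test 4 splits keep the KO arrays together, with 0 to 939 genes for the slope and 103 to 1610 for the departure, and the rest gave 0 for the slope and at most 3 for the departure. Both counts thus follow a structure of the samples, the KO arrays standing apart, and neither test decides whether chance gave the order of WT and HET or the departure of HET.

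Genes with an unadjusted p under 0.01 in HET vs WT gather on the chromosome of Foxo1, though only 1 gene was called in that comparison. The tables argue against an even spread over chromosomes (odds ratio 6.80, 95% interval 3.86 to 11.5). Variants travelling with the floxed allele and an effect of 1 lost allele both stay open: either would give KO at least the change of HET, and for genes picked without 1 HET array the median of KO minus that array, in the picked direction, was -0.88 (95% interval -1.63 to 0.48; 15 genes), -0.32 (-0.70 to -0.072; 19 genes) and -0.19 (-0.51 to 0.11; 19 genes) for HET replicates 1, 2 and 3, so 2 of the 3 intervals include 0. Of the 19 genes other than Foxo1 with an unadjusted p under 0.01 over all arrays, 11 had the same direction in KO, 4 of them with a larger change (Gm34303, Noct, Bcl9 and Tifa), and 8 had the opposite one, of which Frrs1 alone was called in KO vs WT (-0.42 in HET and 0.63 in KO, adjusted p = 0.00384), a tally that decides neither explanation since the genes were picked for their change in HET. In the order of tested genes, Noct and Gm34303 stand at places 71 and 81, near Foxo1 at 80, and the others between 250 and 409. The medians above were not split by position, so they do not speak for Noct and Gm34303 alone. The 14 genes without a call in KO vs WT lie 170 to 329 tested genes from Foxo1 with a median of 4 genes to the nearest other one, as close as in a share of 0.0127 of random draws, so a strain segment carried by the HET animals may be a candidate explanation, as a hypothesis from these data.

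As a list, myeloid cell markers were called higher in KO, in cells sorted by B220, PNA and CD95 after B cell enrichment, steps that would remove most myeloid cells. Of 10 markers 4 passed, and the list call was lost with an estimated correlation (camera adjusted p = 0.533). The groups overlap by array: the mean log2 signal was 7.19 on WT replicate 1, 6.69 on KO replicate 3 and highest, 7.66, on HET replicate 3. Scaling of the arrays stays open: the median rise was 0.51 (95% interval over genes -0.056 to 2.13) and 0.46 (-0.17 to 2.07) under quantile normalization, where the call ended at adjusted p = 0.0516 from 0.0486, with a spread too wide to exclude it. Myeloid cells in the KO sorts stay open too: over 9 tested of 18 further myeloid genes, listed before they were looked at and held by no other list, the median change was -0.084 (95% interval -0.76 to 0.99). Named after their values were seen, Cd36 rose by 1.46 and Ms4a7 by 0.99, Apoe fell by 1.02, and the most abundant ones, Cst3 (5366 in WT, 4669 in KO) and Ctsb (1860 in WT, 1858 in KO), did not pass. An effect of the Foxo1 genotype on these genes within B cells was not tested.

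Marginal zone B cell markers were higher in KO. Scaling of the arrays is argued against, since the median rise was 0.67 (95% interval over genes 0.41 to 0.85) under quantile normalization against 0.72 (0.41 to 0.90). Resting or marginal zone B cells in the KO sorts, which the PNA and CD95 gates would remove, were checked with 15 further genes. These are genes of B cells outside the germinal center, listed before they were looked at, and their median change was 0.063 (95% interval -0.17 to 0.18). The naive and follicular list did not rise either. Its median was -0.18 in KO vs WT (camera adjusted p = 0.173) and -0.29 in KO vs HET (camera adjusted p = 0.0154; adjusted p = 0.194 with an estimated correlation). These values argue against a rise of resting B cell genes as large as that of the marginal zone markers. They do not decide whether some such cells were in the KO sorts, which stays open. Named after their values were seen, Klf3 rose by 0.99, Il10ra by 0.73 and Emp3 by 0.44, Tsc22d3 fell by 0.60, and the most abundant, Vim (6372 in WT, 6643 in KO) and Zfp36l2 (4584 in WT, 4084 in KO), did not pass. Of the 10 marginal zone markers, 4 are also in other lists, and an effect of the Foxo1 genotype on them within GC B cells was not tested.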

How the results depend on the processing

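The Xist block and the fits without genes on the chromosome of Foxo1 were chosen after seeing the data. Of the values that answer a comparison, 229 stayed within their limits and 29 moved; of the named-gene values, 4321 kept their call or lack of one, 264 lost it, 47 gained one and 3 reversed; of the gene-list values, 647, 61 and 9. The cause was not tested unless stated. HET vs WT gave 3 genes with robust eBayes, 3 with array weights, 3 in a fit of only the 6 arrays compared and 0 without genes on the chromosome of Foxo1, where the single called gene lies. HET departure from the midpoint gave 31 genes with eBayes without trend. With an estimated correlation, camera called 2 lists in KO vs WT, 0 in HET vs WT and 2 in KO vs HET; fry called 8, 0 and 13, and for HET vs WT no filter gave 2 and the mean of a gene's probe sets 1. Reversed values were Cenpa in KO vs HET, 0.26 without probe sets of shared suffix, and Uqcrq in KO vs WT, 0.16 with the mean of its probe sets and 0.64 without those of shared suffix, where other probe sets enter. With 1 array left out, the counts ranged from 768 to 1183 genes in KO vs WT, 1 to 3 in HET vs WT, 543 to 895 in KO vs HET, 400 to 965 for the slope per allele and 31 to 109 for HET departure, with fewer arrays as part of the cause; the median HET position over the KO vs WT genes ranged from -0.705 to -0.590 and lists in HET vs WT from 0 to 9. No paired analysis was possible because no 2 groups share a number in the sample titles. Signals near the array median, from 42.9 to 48.0, limit what can be said of dim genes.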

Other observations

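The block for the Xist signal and the values of single arrays were chosen only after the result was seen.

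Lists that camera did not call in KO vs WT held single genes that changed. Of 21 migration and chemokine receptor genes, 6 rose, 3 fell and 12 did not pass (7 and 5 adjusted over the list alone; adjusted p = 0.448). Cxcr5, the receptor that draws B cells into follicles, rose by 0.40 (SE 0.065), and S1pr4, a sphingosine phosphate receptor gene, fell by 0.88 (SE 0.14). Of 17 BCL6 repressed genes, 4 rose, 3 fell and 10 did not pass (5 and 3 adjusted over the list alone; adjusted p = 0.496), with Id2, an inhibitor of E proteins, up from 680.8 ± 85.7 to 1623 ± 138 (SD, n = 3). Of 13 memory B cell precursor genes, 3 rose, 3 fell and 7 did not pass (4 and 3 adjusted over the list alone; adjusted p = 0.962): Nt5e, which encodes CD73, fell by 1.88 (SE 0.11), Ski rose by 0.75 (SE 0.16) and Ccr6 by 1.00 (SE 0.21). Of 14 quiescence genes, 1 rose, 2 fell and 11 did not pass (1 and 3 adjusted over the list alone; adjusted p = 0.639), where the median of 0.045 differs in sign from the mean of -0.032 and the test, with the cell cycle inhibitor gene Cdkn1a up by 1.09 (SE 0.23). Of 17 apoptosis regulators, 3 rose, 1 fell and 13 did not pass (4 and 2 adjusted over the list alone; adjusted p = 0.424), with Bid up by 0.24 (SE 0.052), a call lost with the mean of its probe sets and with eBayes without trend (adjusted p = 0.0589 and 0.0534). Of 20 B cell receptor signaling genes, 5 rose, 1 fell and 14 did not pass (6 and 1 adjusted over the list alone; adjusted p = 0.0799), a list called under quantile normalization (adjusted p = 0.00129) and by fry (adjusted p = 0.0150; range over all settings 0.00129 to 0.474), with Pik3ap1, a PI3K adaptor gene, up by 0.42 (SE 0.068). Of 15 immediate early genes, 1 rose, 1 fell and 13 did not pass (1 and 1 adjusted over the list alone; adjusted p = 0.669), with Egr2 down by 0.82, a call lost with eBayes without trend (adjusted p = 0.0547).

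Of 24 PI3K and AKT genes, 2 rose, 2 fell and 20 did not pass (2 and 2 adjusted over the list alone; adjusted p = 0.969), where median and mean (0.0081 and 0.0065) lie above 0 and the test pointed down. Akt1 fell by 0.34 (SE 0.064), a call lost with the mean of its probe sets (adjusted p = 0.0723). Of 16 NF-kB and CD40 response genes, 2 rose, 1 fell and 13 did not pass (2 and 1 adjusted over the list alone; adjusted p = 0.962), with Tnip1, an NF-kB inhibitor gene, up from 1601 ± 151 to 2384 ± 178 (SD, n = 3). Of 17 antigen presentation genes, 3 rose, 1 fell and 13 did not pass (3 and 1 adjusted over the list alone; adjusted p = 0.342): Icosl, the ligand gene of ICOS on T cells, rose by 0.34 (SE 0.056), or by 0.60 with the mean of its probe sets, and Marchf1 fell by 0.29 (SE 0.06). Of 16 glycolysis genes, 2 rose, 2 fell and 12 did not pass (2 and 2 adjusted over the list alone; adjusted p = 0.519), where the median of -0.071 and the test lie below 0 and the mean is 0.0013, with Pfkfb3 up by 0.45 (SE 0.083) and Tpi1 down by 0.31 (SE 0.067), a call lost without HET replicate 3 (-0.21, adjusted p = 0.11). In that fit another of the 3 probe sets of Tpi1 stood for the gene, so the loss reflects the choice of probe set. Of 27 class switching and hypermutation genes, 3 fell and 24 did not pass (3 adjusted over the list alone; adjusted p = 0.255), among them Batf. Of 28 MYC targets, 1 fell and 27 did not pass (0 adjusted over the list alone; adjusted p = 0.173). Of 15 heat shock and stress genes, 1 rose and 14 did not pass (1 adjusted over the list alone; adjusted p = 0.833). Among 26 ribosomal protein genes (adjusted p = 0.496) and 19 interferon response genes (adjusted p = 0.173), limma called 0 (0 adjusted over the list alone; 1 and 5 at an unadjusted p under 0.05), with medians of -0.016 and -0.20.

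Other values belong to single arrays. The mean Xist signal lay between 10.8 and 31.4 on WT replicate 1, KO replicate 3 and HET replicates 1 and 2, and between 5084 and 5828 on the other 5 arrays, and with the Xist split as a block 1251 genes were called in KO vs WT. That block ended the calls of the myeloid list (adjusted p = 0.0589), Gprc5b, Atp5b and Pdpk1 (adjusted p = 0.0507, 0.0553 and 0.0515) in KO vs WT, of the interferon list in HET vs WT (adjusted p = 0.450) and of the FOXO1 target list, Sdhb and Vav2 in KO vs HET (adjusted p = 0.0631, 0.0605 and 0.0505). The mean hybridization control signal was 11284 on WT replicate 3 and between 8173 and 9857 on the other arrays. The mean log2 signal of the myeloid markers was 7.19, 6.13 and 5.59 on the WT arrays, 6.22, 6.47 and 7.66 on the HET arrays and 7.49, 7.34 and 6.69 on the KO arrays. For the marginal zone markers it lay between 9.81 and 9.89 on the WT and HET arrays and between 10.46 and 10.61 on the KO arrays. Over the 14 genes of the chromosome of Foxo1 without a call in KO vs WT, the median size of the HET change was 0.85, 0.77 and 0.57 for HET replicates 1, 2 and 3, and HET replicate 1 had the largest change in 11 of the 14.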
